A study of Mus musculus with 6 samples.

How the data were processed

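RNA was measured in 6 samples of mouse neutrophils by RNA sequencing. Per the labels, the cells were sorted from the bone marrow of C57BL/6 mice as positive for CD45, CD11b and Ly6G, and were kept for 6 hours with lipopolysaccharide (LPS), either alone or together with resveratrol at an amount the labels write as 25 μmol. RNA was taken with Trizol, and libraries were made with a TruSeq RNA kit and read on a HiSeq instrument, per the labels' protocols. The 6 samples form 2 groups of 3, LPS and LPS+resveratrol, each with replicate numbers 1 to 3. The series text speaks of duplicates, while 3 samples per group are labelled. No sample without LPS is part of what was analysed here.

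The deposited table holds counts, whole numbers per Ensembl gene ID and sample, without normalization. Bowtie 0.12.2 and the genome build mm8 are named in the submitters' processing notes. The program that counted the reads, its annotation and its use of strand are not given in the sources used here. The gene IDs match a later annotation than that build, so no coordinates are printed. Of 25663 IDs, 25595 were matched to a symbol, and where several IDs had the same symbol, the ID with the most counts kept it. Il36g is listed under its older symbol Il1f9.

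The total count per sample was between 18141352 and 19928153. The comparison without LPS+resveratrol replicate 1 is called the 5-library fit. Genes with enough counts were kept by edgeR's filterByExpr (minimum count 10), which left 13468 genes holding at least 99.82% of each sample's counts. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood test of group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM on the TMM-scaled library totals, as mean ± SD over 3 samples. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. On simulated counts for the same 13468 genes, with 200 changed genes in each of 10 draws, the test over 6 samples recovered 29.5% of 2-fold and 1.7% of 1.5-fold changes, and 9.83% of its calls were unchanged genes. In the simulated comparison without LPS+resveratrol replicate 1 these values were 75.9%, 58.2% and 10.9%. No simulated call had the wrong sign. Both shares of unchanged genes among the calls exceeded the threshold of 0.05. Each gene was given the same spread in every simulated library, so none stood apart as LPS+resveratrol replicate 1 did in the data.

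Gene lists were tested with camera (limma 3.58.1) on edgeR's values, with a preset correlation of 0.01 between genes, and adjusted over the 22 response lists with at least 5 tested members. The 9 lists of cell type markers, 6 of them with at least 5 tested members, formed a family of their own. Each list test was repeated with the correlation estimated from the data. That version gave larger p-values even where the estimate lay below the preset one. For p53 targets it was −0.029, and the unadjusted camera p went from 1.46e-05 to 0.0104. A call lost in that version thus does not by itself show correlation between the genes of a list. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named are the 10 genes with the largest rise and the 10 with the largest fall that passed the threshold, had a mean at or above the median of tested genes and did not overlap between groups, without unnamed gene models. Also named are 18 fixed genes, and from each response list up to 4 members with the smallest adjusted p, or the 2 most abundant where none passed. The rule named 79 genes, and any gene named outside it is said to be so chosen.

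The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, unscaled totals, no filter, a filter of at least 50 counts in at least 3 samples, the replicate number as a block, a 2-fold minimum, leaving out each sample, fry and camera on ranks. Alternatives for normalized values did not apply to counts. Library quality weights, offsets for transcript length and GC content, and an estimated correlation without LPS+resveratrol replicate 1 were added after the data were seen. Lengths and GC content were medians over a gene's protein-coding transcripts in GENCODE M21, or over all of its transcripts where it has no protein-coding ones, known for 99.8% of tested genes. Within groups, no 2 samples had identical counts. Over genes with at least 20 counts in a pair, the chi-square statistic per degree of freedom was at least 3.3 in every pair, so all 6 samples were counted separately.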

Results

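Neutrophils are short-lived white blood cells that the bone marrow releases in large numbers, and LPS is a bacterial cell wall component that activates them. Resveratrol is a plant polyphenol. RNA was sequenced from sorted mouse bone marrow neutrophils after 6 hours with LPS (n = 3) or with LPS and resveratrol (n = 3). The single comparison asks which transcripts resveratrol changed in LPS-stimulated neutrophils, and the series places that question in liver ischemia-reperfusion injury and the ERK pathway. Total counts were 18141352, 18561974 and 18687052 in the LPS samples and 18799235, 18478832 and 19928153 in the LPS+resveratrol samples. The labels do not say that the samples of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical.

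With resveratrol, the lists of genes that ERK signalling or interferon induces were lower and those of NRF2 and p53 targets were higher (camera with a preset correlation). All 4 list calls were lost with adjusted p between 0.0632 and 0.0815 with an estimated correlation. That estimate was 0.057 for ERK-responsive, 0.095 for interferon-stimulated and 0.176 for NRF2 target genes. For p53 targets it was −0.029, below the preset 0.01, so correlation alone does not account for that loss. The mitotic genes Ccnb1 and Plk1 and the growth factor and chemokine genes Csf3, Csf1, Ccl2 and Ccl7 fell. The G-CSF gene Csf3 fell by 2.48 ± 0.248 and the ERK-responsive Egr3 by 2.01 ± 0.16 (log2 fold change ± SE, n = 3 each), and the antioxidant gene Srxn1 rose by 1.01 ± 0.103. Il1b and Tnf had log2 fold changes of −0.16 and −0.25 and did not pass. The calls on single genes rest on 6 libraries of which 1 stood apart, as described next.

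Transcripts of mature neutrophils were abundant, with S100a9 at 22350 ± 1060 CPM (SD, n = 3) in the LPS group. LPS+resveratrol replicate 1 stood apart from the other 5 libraries. Its correlation of log2 CPM with them across genes was between 0.954 and 0.964, while the highest correlation of each of the others was at least 0.99. Of 3268 genes with a mean of at least 50 CPM, 252 lay at least 2-fold from the mean log2 level of the other 2 libraries of its group, against 3 to 4 for each LPS library and 34 and 41 for LPS+resveratrol replicates 2 and 3. The counts for replicates 2 and 3 include replicate 1 in their reference. Between those 2 libraries the chi-square statistic per degree of freedom was 3.3, the lowest of the pairs within groups. S100a8 was at 2579 CPM in LPS+resveratrol replicate 1, against 11420 and 11210 CPM in LPS+resveratrol replicates 2 and 3. Ribosomal protein genes took 0.455% of the counts of replicate 1 and at least 0.927% in each other library. Genes with median transcripts under 1 kb lay 0.34 below the other LPS+resveratrol libraries on the log2 scale (median deviation −0.34), and those over 4 kb lay 0.36 above. Genes with a GC content over 55% had a median deviation of −0.39, and those under 45% of 0.28. Counts of genes called over all tested genes are therefore also given without this library, which was decided after the data were seen; counts adjusted over a list alone are for 6 libraries.

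**Figure D1:**
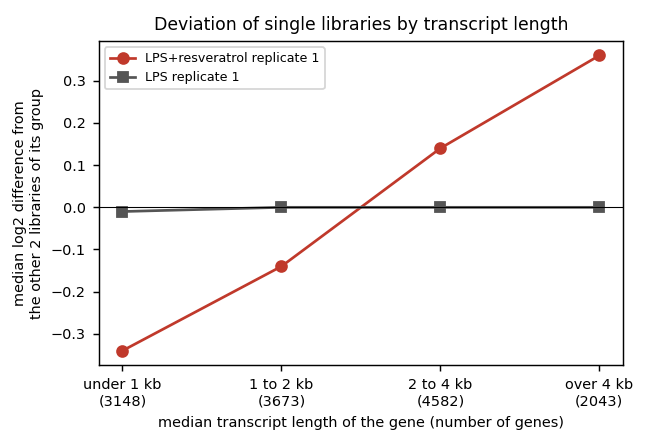
Median log2 difference (vertical axis) of LPS+resveratrol replicate 1 (red circles) and of LPS replicate 1 (grey squares) from the other 2 libraries of its group, by median transcript length of the gene (horizontal axis, with the number of genes). The red line goes from −0.34 under 1 kb to 0.36 over 4 kb, and the grey line stays between −0.01 and 0.

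Resveratrol changed 247 of 13468 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 90 were higher and 157 lower. At least 2-fold changes numbered 28 higher and 60 lower, and 84 and 179 without LPS+resveratrol replicate 1. Without LPS+resveratrol replicate 1, 1634 genes were higher and 1786 lower, and DESeq2 called 1168 higher and 1163 lower. The edgeR calls of that fit held all 247 in the same direction, which the shared libraries make likely. The biological coefficient of variation was 19.8% over 6 libraries and 7.4% over those 5. Leaving out any 1 of the other 5 libraries instead gave 0 calls with edgeR, with between 1564 and 2721 genes at an unadjusted p under 0.05. All 247 genes kept their sign in each of those fits, which their selection on the same 6 libraries makes likely. In the same fits limma-voom called 0 genes and DESeq2 called 72 to 285 genes higher and 103 to 300 lower. These losses hold for each single gene given below as changed over 6 libraries, 49 of the 79 named ones among them, and each remained called without LPS+resveratrol replicate 1. With LPS+resveratrol replicate 1 included, 4479 tested genes (33.3%) had no overlap between the groups, where chance gives 10% on average. Genes vary together across libraries and the share was not computed for other groupings, so this comparison is not a test.

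Genes of mitosis, of Fc receptor and scaffold signalling and of ubiquinone synthesis were among the 10 with the largest falls. Cass4 (ENSMUSG00000074570), a docking protein of the Cas scaffold family, fell from 31.3 ± 1.78 to 8.44 ± 0.188 CPM (SD, n = 3 each), a log2 fold change of −1.89 ± 0.112 (SE; edgeR adjusted p = 0.0049). Ube2c and Cdc20, which act with the anaphase-promoting complex, had log2 fold changes of −1.87 ± 0.216 and −1.86 ± 0.235. The cyclins Ccnb1 and Ccnb2 and the mitotic kinase Plk1 followed with −1.43, −1.33 and −1.29. Camkk1, a calmodulin-dependent kinase kinase, had −1.76, and the high-affinity IgG receptor Fcgr1 had −1.46. The G protein-coupled receptor Gpr35 fell by 1.42 and Coq2, an enzyme of ubiquinone synthesis, by 1.36 on the log2 scale. Among the 10 largest rises, Aplp2 (ENSMUSG00000031996), a relative of the amyloid precursor protein, went from 67.9 ± 3.74 to 176.5 ± 31.7 CPM (SD, n = 3 each; log2 fold change 1.38 ± 0.146 SE, edgeR adjusted p = 0.0191). Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose by 1.17 ± 0.169, and Mylip, a ubiquitin ligase that acts on the LDL receptor, by 1.14 ± 0.174. Fzd5, a Wnt receptor, rose by 1.16, and Zfand4 by 1.22. Sesn3, a sestrin, rose from 11.4 ± 0.738 to 25.0 ± 5.48 CPM and Mapkbp1 from 7.59 ± 0.727 to 16.6 ± 4.34 CPM. Efcab5, Sned1 and Tex15 rose to 3.04, 2.92 and 2.39 times the LPS level, with their highest values in LPS+resveratrol replicate 1 (25.6, 39.7 and 46.8 CPM), and to 2.35, 2.28 and 1.95 times without it. The calls on Efcab5, Sned1 and Mapkbp1 were lost with limma-voom (adjusted p = 0.0501, 0.0501 and 0.064). In GENCODE M21, Cass4 shares 21.2% of its exon bases with Gm14455, Ube2c 22.8% with Tnnc2, Fzd5 17.8% with Gm38058 and Sned1 19.5% with Mterf4, each on the opposite strand. Reads of such pairs cannot be told apart without strand.

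**Figure D2:**
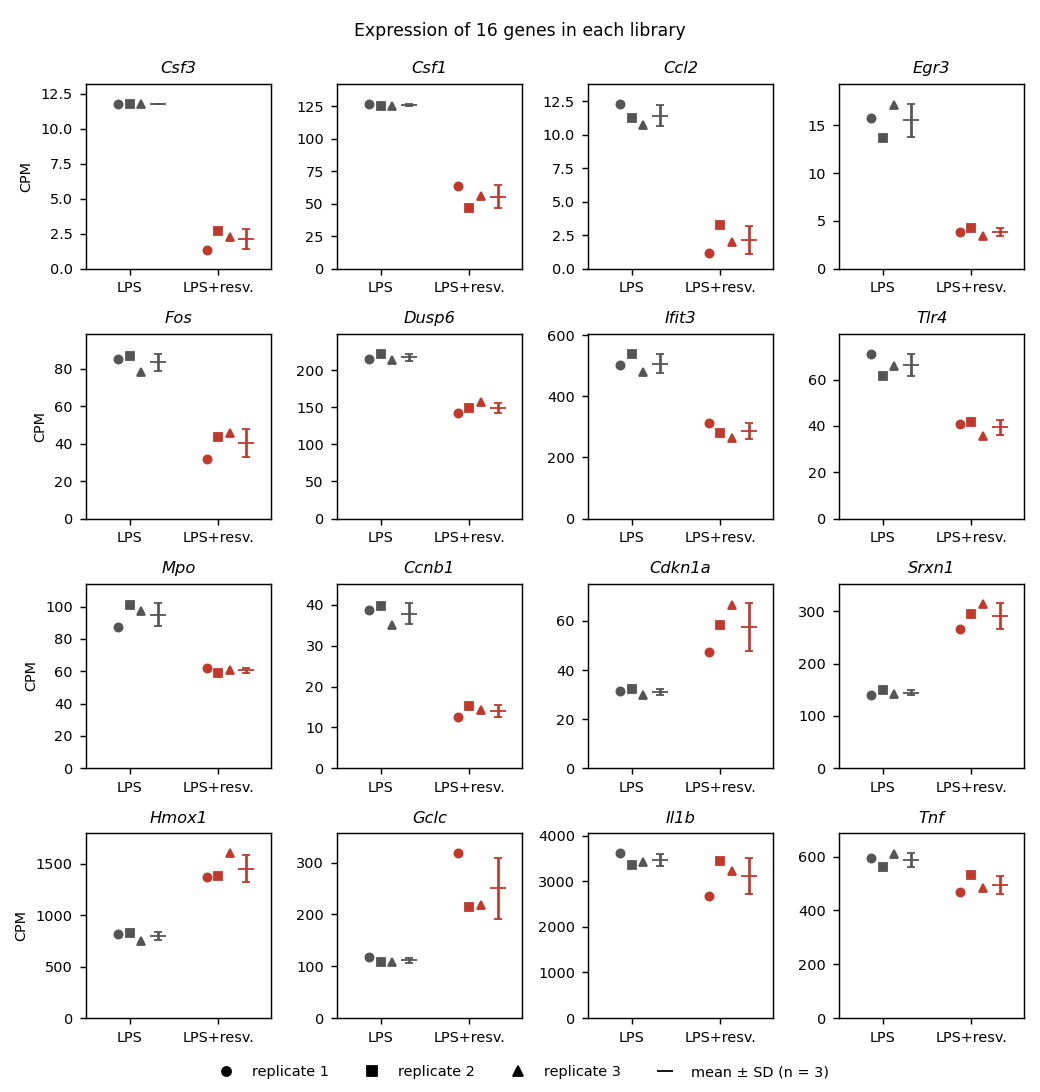
CPM (vertical axes, each from 0) of 16 named genes in each library, LPS in grey and LPS+resveratrol in red, with replicates 1, 2 and 3 as circles, squares and triangles and the mean ± SD (n = 3) beside them. The groups do not overlap for Csf3, Egr3, Ccnb1, Srxn1 or Hmox1, and overlap for Il1b.

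Among genes that ERK signalling induces, Egr3, an early growth response factor, went from 15.5 ± 1.72 to 3.85 ± 0.452 CPM (SD, n = 3 each; log2 fold change −2.01 ± 0.16 SE, edgeR adjusted p = 0.0106). Fos, a subunit of the AP-1 transcription factor, fell from 83.5 ± 4.65 to 40.4 ± 7.41 CPM, Egr2 fell by 0.92 on the log2 scale, and Dusp6, a phosphatase that removes phosphate from ERK, fell by 0.54. Of 19 measured members of the ERK-responsive list 4 fell, 0 rose and 15 did not pass; 7 fell and 1 rose when adjusted over the list alone. As a group they were lower (camera adjusted p = 4.82e-08, median log2 fold change −0.44), with adjusted p = 0.0632 with an estimated correlation. With length and GC offsets Egr2 had a log2 fold change of −0.72 and did not pass (edgeR adjusted p = 0.0613). Egr1 (log2 fold change −0.44, edgeR adjusted p = 0.273) and Spry2 (−0.77, 0.193) did not pass. Without LPS+resveratrol replicate 1, 9 members fell and 1 rose. Etv5 was that member, named after its values were seen, with a log2 fold change of 0.74 in that fit.

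The components of the MAP kinase cascade itself showed 0 calls among 21 members with edgeR, and 1 rose when adjusted over the list alone. Mapk3 was at 194.9 ± 3.97 CPM with LPS and 182.1 ± 12.1 CPM with resveratrol (SD, n = 3 each; edgeR adjusted p = 0.591). Mapk14, among the most abundant members, had a log2 fold change of 0.26 that did not pass, and 0.17 without LPS+resveratrol replicate 1 (edgeR adjusted p = 0.0144). The list as a group did not pass (camera adjusted p = 0.0726). It passed in 3 of 16 settings, among them length and GC offsets (camera adjusted p = 0.0223). Without LPS+resveratrol replicate 1, 6 members were higher and 3 lower, with a log2 fold change of −0.16 for Mapk3 (edgeR adjusted p = 0.0136). LPS+resveratrol replicate 1 had a median deviation of 0.15 over this list.

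Colony-stimulating factors, a subunit of interleukin 12 and monocyte chemoattractants fell, while interleukin 10 and an interleukin 36 gene rose. Csf3, which encodes G-CSF, the main growth factor of neutrophils, fell from 11.8 ± 0.0131 to 2.1 ± 0.712 CPM (SD, n = 3 each; log2 fold change −2.48 ± 0.248 SE, edgeR adjusted p = 0.0191). Csf1 (M-CSF) fell from 125.8 ± 0.855 to 55.5 ± 8.63 CPM and Il12a from 45.6 ± 2.1 to 24.4 ± 1.21 CPM. Il1f9, now named Il36g, rose from 1270 ± 73.2 to 2011 ± 186 CPM. The other call was Il10, outside the naming rule and named because the list had 5 calls in all, with a log2 fold change of 1.01. Of 17 cytokine genes measured, 3 fell, 2 rose and 12 did not pass; adjusted over the list alone, 6 fell and 2 rose. The cytokine list was lower as a group (camera adjusted p = 0.000182, median −0.38), with adjusted p = 0.0815 with an estimated correlation. Over 5 libraries (without LPS+resveratrol replicate 1), 10 fell and 3 rose. The chemokines Ccl2, Ccl7 and Cxcl10 fell, with log2 fold changes of −2.41, −2.54 and −0.70, and the other 12 of 15 measured did not pass; adjusted over the list alone 3 fell and 0 rose. Ccl7 was at 1.68 ± 0.255 CPM with LPS, a low level, and had no adjusted p in DESeq2. The chemokine list was lower (camera adjusted p = 1.35e-05, median −0.39), with adjusted p = 0.3 with an estimated correlation and 0.0794 with fry, and LPS+resveratrol replicate 1 had a median deviation of −0.75 over it. Without that library, 5 fell and 2 rose.

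Il1b and Tnf, which encode major inflammatory cytokines, did not pass over 6 libraries. Il1b was at 3471 ± 133 CPM with LPS and 3114 ± 398 CPM with resveratrol (SD, n = 3 each; edgeR adjusted p = 0.488), and Tnf at 588 ± 24.9 and 493.6 ± 33.4 CPM (edgeR adjusted p = 0.226). Cxcl2, Cxcl1, Ccl3 and Il6 had log2 fold changes of −0.56, −0.11, −0.03 and 0.27 and did not pass. When LPS+resveratrol replicate 1 was left out, Tnf fell by 0.22 on the log2 scale, Il6 rose by 0.49 and Ccl3 rose by 0.14, while Il1b had −0.07, Cxcl2 −0.36 and Cxcl1 0.18 and did not pass (edgeR adjusted p = 0.306, 0.105 and 0.52). The NF-kB feedback genes had 0 calls among 19 members with edgeR (1 higher and 1 lower when adjusted over the list alone) and a median log2 fold change of 0.01 (camera adjusted p = 0.974). Nfkbia, the NF-kB inhibitor that NF-kB itself induces, was at 1046 ± 59.3 and 797.8 ± 157 CPM (edgeR adjusted p = 0.233), and had a log2 fold change of −0.25 without LPS+resveratrol replicate 1 (edgeR adjusted p = 0.000366). Tnip1 and Irak3, the most abundant members, had log2 fold changes of 0.05 and 0.34, and of −0.14 and −0.01 without that library, where Tnip1 passed (edgeR adjusted p = 0.0325). Without it, 5 members were higher and 5 lower.

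Of interferon-stimulated genes, which cells switch on against viruses, all 24 measured had negative log2 fold changes, with a median of −0.50. Ifit3 fell from 507 ± 30.6 to 285.9 ± 25.3 CPM, Ifit2 from 345.5 ± 20.1 to 215.6 ± 29.4 CPM, and Rsad2 from 2860 ± 104 to 1978 ± 70.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.0243, 0.0486 and 0.0378). Over all tested genes 3 fell, 0 rose and 21 did not pass, and 16 fell when adjusted over the list alone. The list was lower by camera (adjusted p = 2.63e-11), with adjusted p = 0.0632 with an estimated correlation. Without LPS+resveratrol replicate 1 all 24 fell, with a median of −0.51. Ifit3 has the near-identical neighbour Ifit3b, and members of the Oas1 family resemble each other, so the split of reads among such copies is uncertain.

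Tlr4, the LPS receptor, fell from 66.2 ± 4.83 to 39.3 ± 3.26 CPM (SD, n = 3 each; log2 fold change −0.75 ± 0.115 SE, edgeR adjusted p = 0.0312), and the peptidoglycan sensors Nod1 and Nod2 fell by 0.73 and 0.64 on the log2 scale. The LPS co-receptors Cd14 and Ly96 and the lipoprotein receptor Tlr2, named after their values were seen, did not pass (edgeR adjusted p = 0.311, 0.467 and 0.0958); without LPS+resveratrol replicate 1, Cd14 and Tlr2 fell by 0.21 and 0.53 on the log2 scale (edgeR adjusted p = 0.00788 and 6.38e-10) and Ly96 did not pass (0.407). Tlr4, Nod1 and Nod2 were the 3 calls among 17 measured LPS receptor and inflammasome genes, of which 0 rose and 14 did not pass; 7 fell when adjusted over the list alone. The list was lower (camera adjusted p = 0.00294, median −0.22), with adjusted p = 0.0815 with an estimated correlation, and 8 members fell without LPS+resveratrol replicate 1. Of 14 LPS-induced effector genes, only F10 (coagulation factor X) passed, falling from 285.7 ± 3.74 to 157.5 ± 7.19 CPM, and 2 fell when adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, was at 85.6 ± 3.51 and 53.6 ± 8.04 CPM and did not pass (edgeR adjusted p = 0.0566); without LPS+resveratrol replicate 1 it fell by 0.81 on the log2 scale. The effector list did not pass (camera adjusted p = 0.395), and without that library 5 members were higher and 3 lower.

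Among targets of NRF2, the transcription factor of the oxidative stress response, Srxn1 (sulfiredoxin) rose from 144.1 ± 4.82 to 290.8 ± 24 CPM (SD, n = 3 each; log2 fold change 1.01 ± 0.103 SE, edgeR adjusted p = 0.0191). Gclm, the partner of Gclc, rose from 236.3 ± 0.956 to 411.2 ± 6.28 CPM, Hmox1, the heme-degrading heme oxygenase, from 795.5 ± 40.4 to 1449 ± 131 CPM, and the cystine transporter Slc7a11 from 1818 ± 53.2 to 3460 ± 439 CPM. Of 18 measured members 7 rose, 0 fell and 11 did not pass; 8 rose when adjusted over the list alone. As a group they were higher (camera adjusted p = 5.72e-11, median 0.42), with adjusted p = 0.0815 with an estimated correlation. In the 5-library fit, without LPS+resveratrol replicate 1, 16 of 18 rose and 0 fell. The p53 target list was also higher (camera adjusted p = 4.59e-05, median 0.36), with adjusted p = 0.0632 with an estimated correlation. Of its 11 measured members, 3 rose, 0 fell and 8 did not pass, and 4 rose when adjusted over the list alone. The 3 were Cdkn1a, the cell cycle inhibitor p21, at 31.2 ± 1.26 and 57.4 ± 9.72 CPM, Ccng1 at 60.1 ± 4.65 and 98.2 ± 5.7 CPM, and Trp53inp1 at 410.9 ± 15.3 and 664 ± 24 CPM. Over 5 libraries (without LPS+resveratrol replicate 1), 7 rose. Of 6 aryl hydrocarbon receptor targets only Tiparp had enough counts, with a log2 fold change of 0.14 (edgeR adjusted p = 0.61), and −0.02 without LPS+resveratrol replicate 1 (edgeR adjusted p = 0.852). Sirt1, a deacetylase often studied with resveratrol, was at 45.5 ± 3.35 and 65.3 ± 11.4 CPM (edgeR adjusted p = 0.127), and rose by 0.36 without LPS+resveratrol replicate 1 (edgeR adjusted p = 0.000299). The sirtuin and FOXO list had 0 calls among 10 members with edgeR, and 2 rose when adjusted over the list alone. It did not pass as a group (camera adjusted p = 0.682). Its most abundant members, Foxo3 and Sirt7, had log2 fold changes of 0.11 and 0.07 that did not pass. Both values shifted without LPS+resveratrol replicate 1, to −0.003 and 0.28 (edgeR adjusted p = 0.978 and 0.00016), where 4 members were higher and 2 lower.

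Cell cycle genes moved in opposite directions. The mitotic genes Ccnb1, Ccnb2, Plk1, Ube2c and Cdc20 fell, Ccnb1 from 37.8 ± 2.54 to 14.1 ± 1.42 CPM (SD, n = 3 each; edgeR adjusted p = 0.0158), and these were the 5 calls among 20 members, of which 0 rose and 15 did not pass. Adjusted over the list alone, 7 fell and 5 rose. The list was lower by camera (adjusted p = 0.00294) and had adjusted p = 0.0816 with an estimated correlation. The call was also lost on ranks (adjusted p = 0.952) and with library quality weights (adjusted p = 0.16). Its median and mean differed in sign, at 0.07 and −0.30, and 10 of 20 members lay below 0. When LPS+resveratrol replicate 1 was left out, 10 fell and 6 rose (median −0.09). Among the 6 were Pcna, Rrm2, Mcm4 and Tyms, which serve DNA replication and were named after their values were seen, with log2 fold changes of 0.68, 0.73, 0.44 and 0.62 in that fit.

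Of 6 primary granule genes, which neutrophil precursors transcribe early, 1 fell. Mpo (myeloperoxidase) fell from 94.95 ± 7.03 to 60.63 ± 1.61 CPM (SD, n = 3 each; log2 fold change −0.65 ± 0.103 SE, edgeR adjusted p = 0.0338). With length and GC offsets it had −0.48 and did not pass (edgeR adjusted p = 0.0718). All 6 members had negative log2 fold changes, and 6 fell when adjusted over the list alone. The list was lower (camera adjusted p = 1.95e-05, median −0.75), with adjusted p = 0.176 with an estimated correlation. LPS+resveratrol replicate 1 had a median deviation of −0.84 over this list; without it 6 fell, with a median of −0.55. Secondary and tertiary granule genes had 0 calls among 12 members with edgeR (5 higher and 2 lower when adjusted over the list alone). The list did not pass (camera adjusted p = 0.404), except in 1 of 16 settings. Ngp and Lcn2, its most abundant transcripts, were at 17750 ± 979 and 17700 ± 1080 CPM with LPS and had log2 fold changes of 0.27 and 0.06 that did not pass, and of 0.29 and 0.26 without LPS+resveratrol replicate 1 (edgeR adjusted p = 1.11e-06 and 1.43e-05). In the 5-library fit, without LPS+resveratrol replicate 1, 6 members were higher and 2 lower. NADPH oxidase genes had 0 calls among 7 members with edgeR (camera adjusted p = 0.974). Cybb, the catalytic subunit, was at 3299 ± 144 and 4303 ± 514 CPM (edgeR adjusted p = 0.142) and Ncf1 had a log2 fold change of −0.03; 2 members were higher without LPS+resveratrol replicate 1, where Cybb had 0.28. Of 15 chemotaxis and adhesion receptors, only Ccr1, a chemokine receptor, passed, falling from 134.9 ± 5.5 to 84.1 ± 8.06 CPM, with 2 lower and 1 higher when adjusted over the list alone. That list did not pass (camera adjusted p = 0.974), its median was 0.03 and its mean −0.01, and 3 members were higher and 3 lower without LPS+resveratrol replicate 1.

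Of the cholesterol synthesis genes, Lss, the enzyme that forms lanosterol, fell from 19.8 ± 0.674 to 12.1 ± 0.935 CPM (SD, n = 3 each; edgeR adjusted p = 0.0366) as the single call among 19 members, 18 of which had negative log2 fold changes, and 9 fell when adjusted over the list alone. The list was lower (camera adjusted p = 1.04e-05, median −0.37), with adjusted p = 0.0632 with an estimated correlation; without LPS+resveratrol replicate 1, 15 fell and 1 rose. Of 9 LXR targets only Mylip passed (117.4 ± 1.28 and 258.4 ± 64.3 CPM), with 3 higher and 1 lower when adjusted over the list alone. The list did not pass with camera (adjusted p = 0.217) but passed with fry (adjusted p = 0.0278). Without that library, 3 were higher. Among 19 apoptosis genes, Bak1, which permeabilises mitochondria, fell by 0.75 on the log2 scale (edgeR adjusted p = 0.0284; −0.51 and 0.0708 with length and GC offsets), and 3 fell and 2 rose when adjusted over the list alone. The apoptosis list was lower (camera adjusted p = 0.011, median −0.21), with adjusted p = 0.354 with an estimated correlation, 0.0794 with fry and 0.0626 by camera without LPS+resveratrol replicate 1, where 9 fell and 3 rose; over its 16 settings the adjusted p lay between 0.00203 and 0.466. Bcl2a1a, Bcl2a1b and Bcl2a1d are near-identical copies whose reads cannot be split with certainty. Glycolysis genes had 0 calls among 18 members with edgeR, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.46). Pkm and Aldoa had log2 fold changes of 0.17 and 0.14 that did not pass. Without LPS+resveratrol replicate 1, where 4 members were higher and 5 lower, they had 0.11 and 0.31 (edgeR adjusted p = 0.0864 and 1.11e-05), and with length and GC offsets Aldoa had 0.41 (edgeR adjusted p = 0.0477). Amino acid and ER stress response genes had 0 calls among 16 members with edgeR, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.974, median −0.01, mean 0.02). Hspa5 and Herpud1 had log2 fold changes of 0.21 and 0.14 that did not pass; 6 members were higher and 3 lower without LPS+resveratrol replicate 1, where the 2 genes had 0.30 and 0.09 (edgeR adjusted p = 2.85e-05 and 0.236). Oxidative phosphorylation genes had 0 calls among 22 members with edgeR, on either adjustment, and a median of −0.27 (camera adjusted p = 0.0698). These genes passed as a list in 5 of 16 settings. LPS+resveratrol replicate 1 had a median deviation of −0.87 over them; without it the median was −0.03, with 1 higher and 1 lower. Atp5b and Atp5a1 had log2 fold changes of −0.05 and −0.04 over 6 libraries, and of 0.06 and 0.07 without it, and passed in neither.

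**Figure D3:**
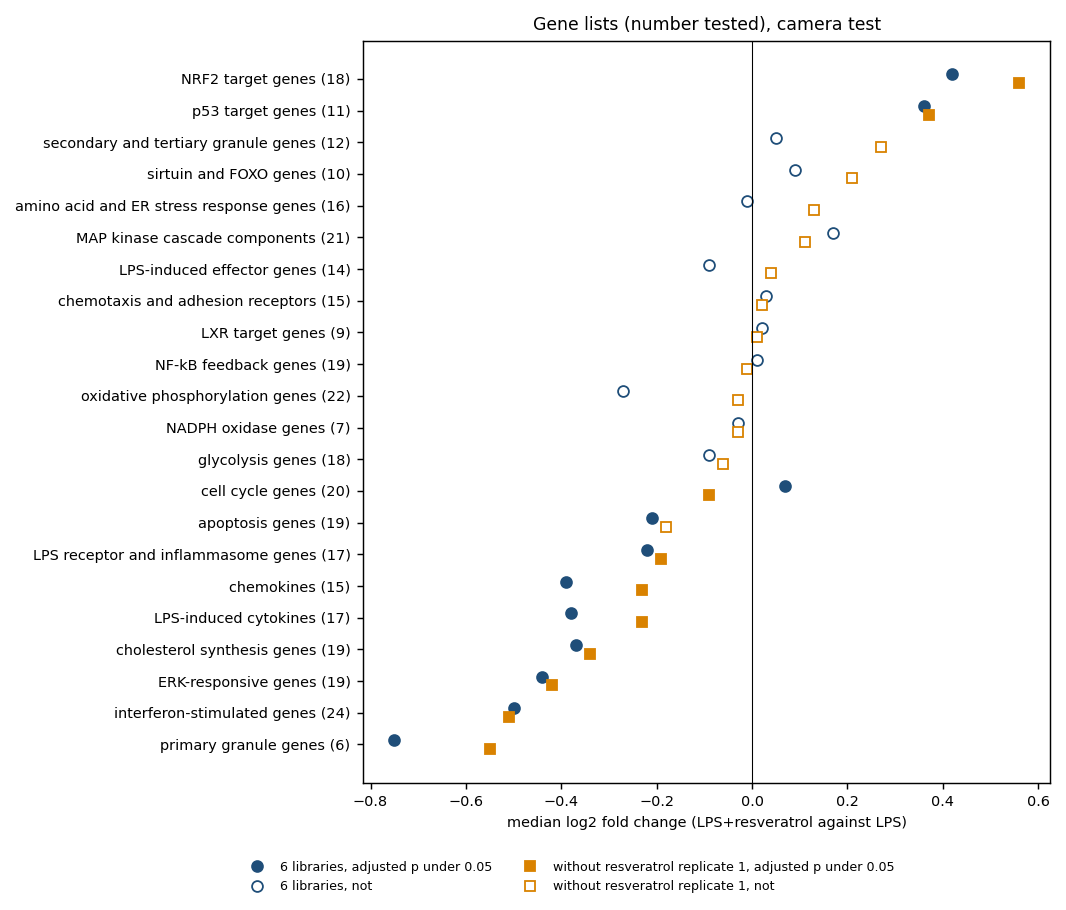
Median log2 fold change (horizontal axis, LPS+resveratrol against LPS) of the tested members of the 22 response lists (vertical axis, number of members in parentheses), over 6 libraries (blue circles) and without LPS+resveratrol replicate 1 (orange squares); filled symbols passed the camera test with a preset correlation. NRF2 targets lie at 0.42 and 0.56, interferon-stimulated genes at −0.50 and −0.51, and oxidative phosphorylation genes move from −0.27 to −0.03.

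In all, 2 response lists were higher and 9 lower with resveratrol among the 22 tested by camera with the preset correlation. With an estimated correlation 0 passed, with 8 lists at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 10. Over 5 libraries (without LPS+resveratrol replicate 1), 2 were higher and 8 lower, and with an estimated correlation 0 passed there, with 5 lists at an unadjusted p under 0.05 (lowest adjusted p = 0.123).

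The lists of markers of other cell types did not pass with camera, and among them Adgre1, a macrophage marker, was at 1042 ± 32.3 CPM (SD, n = 3) with LPS. With fry, T and NK cell markers and neutrophil markers passed (fry adjusted p = 0.0157 for each). Monocyte and macrophage markers had a median log2 fold change of −0.21 and a mean of −0.03 over 10 members (camera adjusted p = 0.406). B cell markers had −0.34 and T and NK cell markers −0.56 over 7 members each, and eosinophil, basophil and mast cell markers −0.28 over 7 (camera adjusted p = 0.0795 for each of the 3). Erythroid markers, whose globin copies share reads, had a median of −0.49 over 6 members (camera adjusted p = 0.0857), with a median deviation of −2.32 in LPS+resveratrol replicate 1. Dendritic cell, megakaryocyte and platelet, and progenitor markers had 4 measured members each, too few for the list test, with medians of 0.06, −0.59 and −0.14. Neutrophil markers had a median of 0.17 over 9 members (camera adjusted p = 0.0857) and passed without LPS+resveratrol replicate 1 (median 0.16, camera adjusted p = 0.0407, adjusted p = 0.356 with an estimated correlation). These lists had 0 members called by edgeR over 6 libraries; adjusted over the list alone, 1 monocyte and macrophage marker rose and 3 fell, and 1 eosinophil, basophil and mast cell marker fell. When LPS+resveratrol replicate 1 was left out, 4 neutrophil markers were higher, and 1 monocyte and macrophage marker was higher and 4 were lower. In that fit 3 B cell, 2 T and NK cell, 2 progenitor, 2 eosinophil, basophil and mast cell, 1 erythroid, 1 dendritic cell and 1 megakaryocyte and platelet marker were lower and 0 higher.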

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

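The settings with library quality weights, with offsets for transcript length and GC content, and with an estimated correlation in 5 libraries were chosen after seeing the data. Beside 90 genes higher and 157 lower with resveratrol in edgeR over 6 libraries, DESeq2 called 366 and 413, a test with no filter 153 and 239, the 2-fold change required 28 and 60, library quality weights 1508 and 1559, and length and GC offsets 232 and 286. Leaving out 1 library gave between 0 and 1634 genes higher and between 0 and 1786 lower; the highest counts were those without LPS+resveratrol replicate 1, which had a quality weight of 0.08 against at least 1.49 for each other library. With the replicate number as a block, edgeR called 0 higher and 0 lower, with 2287 genes at an unadjusted p under 0.05, limma-voom 0 and 0, and DESeq2 112 and 185. The correlation of same-numbered libraries' deviations from their group means was 0.02, −0.017 and 0. The large deviation of LPS+resveratrol replicate 1 enters the mean of its group, so these values cannot exclude pairs. The labels do not say that the numbers mark pairs, so they entered only as the alternative block. For lists, 2 higher and 9 lower became 0 and 0 with an estimated correlation, over 6 libraries and over 5; the other list settings stayed within 1.5 times. The direction of Ccl3 and Tnip1, not called over 6 libraries, reversed without LPS+resveratrol replicate 1, with log2 fold changes between −0.178 and 0.135 for Ccl3 and between −0.138 and 0.153 for Tnip1 when each library was left out. Another 7 named genes had the other sign without LPS+resveratrol replicate 1 and were called in neither fit (Cxcl1, Irak3, Tiparp, Foxo3, Ncf1, Atp5b and Atp5a1). The cause of these differences was not tested, except that a 2-fold minimum limits calls by construction. Fewer samples alone do not set the count, since it rose when LPS+resveratrol replicate 1 was left out. The biological coefficient of variation was 19.8% over 6 libraries and 7.4% without that library. In the other settings with 6 libraries, limma-voom ended 3 of the 49 calls on named genes, length and GC offsets 3 (Mpo, Egr2 and Bak1), DESeq2 1 (Ccl7) and the block all 49. What depth limits was not tested. Alternatives for normalized values were not run, since the table holds counts.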

Other observations

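The tests of transcript length and GC content on the library that stood apart and on the 4 falling factor genes, both tests of cells of another type and the test of monocytes were chosen after the values they use had been seen; the splits, the test of a stronger response and both tests on the cell cycle were written before. Genes in the next 2 paragraphs were chosen after their values were seen.

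Zbp1, a sensor of Z-form nucleic acids, fell from 248 ± 10 to 145.6 ± 14 CPM, Isg20, an exonuclease, from 304.8 ± 23.1 to 136.4 ± 30.1 CPM, and Nlrc5, an activator of MHC class I genes, from 200 ± 3.85 to 127.7 ± 12.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.0271, 0.0308 and 0.0366). Genes were also put into 150 groups by the first letters of the symbol, cut short as in Serp. Such a group is not always a gene family, and Ifit, for one, takes in Ifitm symbols. Of the 150 groups, 3 were higher and 11 lower over 6 libraries. Without LPS+resveratrol replicate 1, 1 was higher and 5 lower, and 3 (Ifi, Ifit and Mcm) passed in both. The Ifit group of 12 genes was lower over 6 libraries (median log2 fold change −0.74, camera adjusted p = 7.16e-08). So was the Ifi group of 17 genes (−0.37, 0.00793), beside groups such as Rpl (−0.32, 0.00333) and Nduf (−0.37, 0.00406). Rpl and Nduf did not pass without that library. Without LPS+resveratrol replicate 1, 9 genes of the Ifit group and 14 of the Ifi group fell and 0 rose. Tlr, Parp and Kif were also lower in that fit (camera adjusted p = 0.0478, 0.0214 and 0.0214), and Mcm was higher (0.0243). With an estimated correlation 0 of the 150 groups passed in that fit (camera adjusted p = 0.738 for Ifi and Ifit). Near-identical Ifit and Ifi copies share reads, and both groups include members of the fixed interferon list.

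Among other single genes, Ctss, a cysteine protease, fell from 124.4 ± 9.05 to 62.0 ± 1.43 CPM, Cd68, a lysosomal membrane protein, from 84.2 ± 1.36 to 44.6 ± 2.32 CPM, and Grn (progranulin) from 275.8 ± 7.22 to 152 ± 22.3 CPM (SD, n = 3 each; edgeR adjusted p = 0.0191, 0.0191 and 0.0301). The decoy receptor Il1r2 fell by 1.20 and the transcription factor Bhlhe40 by 0.90 on the log2 scale. Among genes that rose, the glutathione conjugate exporter Abcc1 went from 742.2 ± 5.12 to 1099 ± 39.9 CPM (edgeR adjusted p = 0.0332). Jun, a partner of Fos in AP-1, rose from 58.7 ± 4.71 to 110 ± 8.37 CPM while Fos fell by 1.04 on the log2 scale (edgeR adjusted p = 0.0229 and 0.0284).

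LPS+resveratrol replicate 1 differed from replicates 2 and 3 by an SD of 0.744 in log2 deviations across genes. Transcript length and GC content explained 25.4% of that variance, and offsets that remove such trends gave 518 called genes against 3420 without the library, which argues against the trend as the whole cause but not as a part. A stronger response to resveratrol was tested on 3687 genes with an absolute log2 fold change under 0.1 in replicates 2 and 3. Their SD in replicate 1 was 0.738, 1.17 times that of called genes, where a stronger response would give much less. The sets were not matched for abundance, and low counts widen such an SD, so a stronger response stays open. The first criterion set for RNA from cells of another type, a median deviation above 0.5 for the markers of at least 1 such type, was met by T and NK cell markers at 0.51, with 7 genes of which Cd8a was highest at 4.27 CPM in replicate 1 and Cd3d had −1.17. After that result was seen, the criterion was replaced by the range of the neutrophil markers, which dilution would lower alike and which spanned 2.81, from −2.13 for S100a8 to 0.68 for Mmp8; this argues against such cells, which the Ly6G gate should remove, as the whole cause. A small admixture stays open, as does a difference in RNA integrity, library preparation or culture, which was not tested.

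In the fixed cell cycle list, mitotic genes fell while genes of DNA replication did not, which led to the following tests. In 2 further lists of cell cycle genes not looked at before, and without LPS+resveratrol replicate 1, 34 S phase genes had a median log2 fold change of 0.40 (19 rose and 0 fell) and 35 G2/M genes one of −0.36 (25 fell and 1 rose). Both lists were read in the same libraries that prompted the question, so their directions are not independent support. Over 6 libraries the medians were 0.46 and −0.33, with 3 S phase genes higher and 0 lower and 0 G2/M genes higher and 2 lower. Fewer cycling precursors alone would lower both alike, and the medians differed by 0.75. Their 95% bootstrap intervals, 0.26 to 0.45 and −0.62 to −0.26, came from resampling genes and hold no spread between samples. A loss of precursors beside another change is not excluded. In the same fit all 6 primary granule genes fell (median −0.55). Progenitor markers had a median of −0.3 there, with 2 of 4 lower and 0 higher. The length and GC trend of replicate 1 is argued against by the G2/M median of −0.356 in the fit without that library. What sets the S phase and G2/M genes apart stays open and was not tested.

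Csf1, Csf3, Ccl2 and Ccl7 had log2 fold changes between −2.29 and −1.30 without LPS+resveratrol replicate 1. Loss of monocytes and macrophages, which the Ly6G gate should remove, would lower their markers by a like amount; of 5 markers with at least 5 CPM the one that fell most, Ccr2, had −0.57. This does not exclude such a loss, since Fcgr1, Cd68 and Ctss had −1.30, −0.89 and −0.99, and Csf1r and Adgre1, at 913.8 and 1042 CPM with LPS, could hide it behind a high baseline. The length and GC trend of replicate 1 is argued against by the smallest of the 4 falls, −1.30 without that library and −1.01 with offsets. A loss of monocytes and macrophages and lower transcript levels within neutrophils thus both stay open.

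For the count of changed genes, 1 of 10 splits of the 6 libraries into 3 and 3 gave as many, the real one with 247 genes. The highest other split gave 0 genes with edgeR and 0 with limma-voom, with 101 to 317 genes at an unadjusted p under 0.05. For the count of changed lists, 1 of 10 splits gave as many, the real one with 11. Every other split also gave changed lists, between 2 and 8, though it gave 0 genes. With 10 splits the share is never under 0.1, too few for a test at 0.05.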
